A study of Mus musculus with 60 samples.

How the data were processed

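RNA was sequenced from sorted erythroblasts of mouse fetal liver (C57BL/6), wild type or Gata1s, at E12.5 and E14.5, as poly-A selected, directional libraries, per the labels. The series has 60 samples, of which the 20 RNA-seq libraries were used, and its chromatin samples were not analysed here. The deposited signal is a table of normalised counts per gene, made by the authors from aligned reads, per the labels. TopHat2, HTSeq, DESeq2, Trim Galore and Bowtie2 and the builds mm10 and mm9 are named per the submitters' processing notes, but which tool or build served the RNA libraries is not given in the sources used here. Gene names are those of the table, and GRCm38.p6 was used only to match older symbols and to find neighbours of Gata1.

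The table has 23420 entries, of which 27 carry a date in place of a gene name (0.2 to 0.36% of a library's values) and were left out, as was 1 column matching no sample. The smallest value above 0 of each library was taken as 1 read, and every value was then a whole number of reads within 3e-09 (tolerance 0.001). Recovered reads were 17.9 to 25.7 M in wild type and 13.8 to 32.8 in Gata1s libraries of E12.5 R1/2, 9.3 to 22.6 and 11.1 to 13 in E12.5 R3, 10.9 to 27.1 and 13 to 30.9 in E14.5 R1/2, and 7 to 15.9 and 7.6 to 10.6 in E14.5 R3. Thus 1 read equals 0.36 to 4.72 normalised counts, so a value near 10 rests on few reads, and floors of 3 reads cover counting error only. Replicates of a group correlated at 0.965 to 0.994 and differed by more than counting error, with chi-square per gene of at least 2.6 in all 17 pairs compared.

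Log2 of the normalised count plus 1 was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) for 10720 genes with a mean of at least 10 over all 20 libraries, with 8 group means (genotype, day and sort) and a term for the prefix of the library names (JC or MS). There were 11 residual degrees of freedom, 15.8 with the prior. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes on this scale understate changes of genes with low counts. Comparisons were Gata1s against wild type in each combination and their mean, differences of that effect between days and between sorts, R3 against R1/2 in each genotype, and E14.5 against E12.5 in wild type. All Gata1s R3 libraries have the prefix MS, and 1 of wild type R3 per day. The term for R3 thus rests partly on R1/2 libraries. What the prefixes mean is not given. limma called 992 genes higher and 570 lower in MS. Lists differed too, among them hepatoblast (median -1.8), megakaryocyte (-0.35), red cell membrane (0.27) and late maturation (0.26).

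Gene lists, 27 with 744 entries, were written before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. Of the entries 741 matched a table entry, 14 under an older symbol, and 587 were tested as genes. As lists, only the 25 with at least 2 measured genes were tested. Lists were tested with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members passing are counted over all genes, and where it differs also adjusted over the list alone. Maturation genes were taken from R3 against R1/2 in wild type at the other day (adjusted p under 0.05, at least 2-fold).

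Genes named by symbol follow a rule: per genotype comparison and for their mean, the 6 largest called increases and decreases with a mean of at least 50 and no overlap between libraries, up to 2 members per list with the smallest adjusted p, and Gata1, Gata2 and all globins. For the other comparisons it takes the 5 largest each way and list members. Predicted and sex-linked genes were excluded. The rule gave 609 results, 594 called, of which edgeR missed 11. The text prints 232 of them, 217 called, for 100 genes, chosen after the data were seen, and edgeR called every one of the 217. Some genes under the rule are not reported here.

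Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, upper-quartile scaling and quantile normalisation, no prefix term, libraries of 1 prefix only (MS leaves 1 wild type library per group, JC 1 of each genotype in E14.5 R1/2), replicate numbers as a block, the groups compared only, a 2-fold minimum, robust empirical Bayes, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, reads thinned to the shallowest library, a mean of at least 50 in the groups compared, and the mean of the hepatoblast or the neutrophil and monocyte list as a covariate.

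Simulated test data had 10720 genes, 100 changed by log2 1 and 100 by log2 2. limma recovered 94, 84, 89 and 88% of the smaller changes in E12.5 R1/2, E12.5 R3, E14.5 R1/2 and E14.5 R3, and 98, 96, 97 and 95% of the larger, with 1.5, 8.6, 1.6 and 42.8% false calls. edgeR gave 6.2, 7.2, 4.5 and 5.4%. In E12.5 R3, camera p was 2.3e-15 for 25 genes shifted by 0.5. Random lists (0 of 100 at p under 0.05) do not test correlated genes.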

Results

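Gata1s embryos carry a form of GATA1, a transcription factor of red cell and megakaryocyte development, that lacks its N-terminal part. Erythroblasts of their fetal livers were compared with wild type cells in the R1/2 sort (high CD71, no to medium Ter119) and in the R3 sort (high CD71, high Ter119), at embryonic days E12.5 and E14.5. Values are normalised counts as group mean ± SD over libraries, and log2 differences ± standard error are Gata1s minus wild type unless another comparison is named, with limma adjusted p-values. Wild type and Gata1s libraries number 2 and 4 in E12.5 R1/2, 3 and 2 in E12.5 R3, 2 and 3 in E14.5 R1/2, and 2 and 2 in E14.5 R3. Libraries held 7 to 32.8 M reads. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these samples.

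Gata1 itself had 2820 to 3110 normalised counts in wild type and 3480 to 3760 in Gata1s libraries of E12.5 R1/2, and 7420 to 9070 and 7640 to 7760 in E12.5 R3. The ranges were 2980 to 3010 and 3560 to 3690 in E14.5 R1/2, and 9610 to 10800 and 13700 to 14200 in E14.5 R3. Its log2 difference was 0.29 ± 0.07 in E12.5 R1/2 (adjusted p = 0.0201), -0.12 ± 0.08 in E12.5 R3 (0.265), 0.27 ± 0.08 in E14.5 R1/2 (0.0375) and 0.44 ± 0.09 in E14.5 R3 (0.000985), and its mean over the 4 combinations was 0.22 ± 0.04 (0.000482). In E12.5 R3 its direction turned under quantile normalisation (0.24, called). A count per gene does not show which part of the transcript was present and so does not test the mutation. The call in E12.5 R1/2 was lost without wild type replicate 2 (0.243) or Gata1s replicate 2 (0.0585). That in E14.5 R1/2 was lost without wild type replicate 1 (0.112) or 2 (0.26), Gata1s replicate 1 (0.101), 2 (0.103) or 3 (0.0674), or Gata1s E12.5 R1/2 replicate 1 (0.0529) or 4 (0.0532).

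Gata2, which is active in progenitors and normally switched off by GATA1, was higher in Gata1s cells of both sorts. In E12.5 R3 it rose from 11.5 ± 1.21 to 250 ± 54.9 (4.33 ± 0.40, adjusted p = 1.07e-06) and in E14.5 R3 from 12.9 ± 1.83 to 415 ± 45 (4.93 ± 0.42, 2.71e-07), with no overlap between libraries. In R1/2 the difference was smaller, from 79 ± 56.7 to 177 ± 48.6 at E12.5 (1.32 ± 0.35, 0.0271) and from 64 ± 25.6 to 155 ± 5.26 at E14.5 (1.33 ± 0.38, 0.0341). The R3 difference exceeded that of R1/2 by 3.60 ± 0.56 at E14.5 (0.000417), and the mean over the 4 combinations was 2.98 ± 0.20 (9.15e-09). The E12.5 R1/2 call was lost without wild type replicate 1 (0.639) or Gata1s replicate 1 (0.0785) or 2 (0.0709). The E14.5 R1/2 call was lost without wild type replicate 2 (0.478) or Gata1s replicate 1 (0.0699), 2 (0.0912) or 3 (0.0844).

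**Figure D1:**
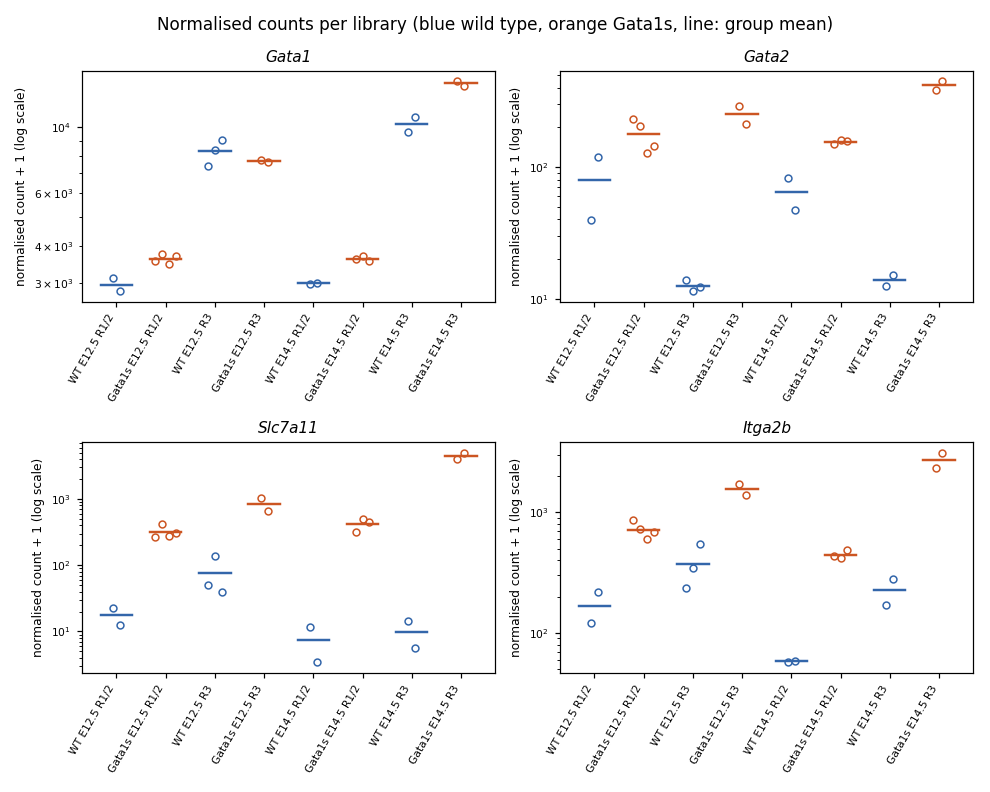
Normalised counts plus 1 on a log scale for Gata1, Gata2, Slc7a11 and Itga2b in each library, with wild type in blue, Gata1s in orange and lines at group means. Gata2 means in E14.5 R3 were 12.9 in wild type and 415 in Gata1s, and those of Slc7a11 were 8.98 and 4500.

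Beta-s, the symbol under which the table lists adult beta globin, fell in Gata1s R3 at E12.5 from 1390000 ± 329000 to 406000 ± 48600, by 2.23 ± 0.39 log2 (adjusted p = 0.000362), or from 7.04% to 2.68% of all values. At E14.5 its share was 12.8% and 9.91% of R3 values (-0.80 ± 0.42, 0.144). In R1/2 it was 18700 ± 12000 against 9720 ± 3530 at E12.5 (-0.85, 0.156) and 92400 ± 78500 against 41300 ± 7180 at E14.5 (-0.97, 0.116), and over the 4 combinations it fell by 1.22 ± 0.20 (0.00011). Under quantile normalisation the E12.5 R3 call ended (-0.39) and E12.5 R1/2 passed. Beta-s passed in E14.5 R1/2 without wild type replicate 1 (0.0132) or Gata1s replicate 1 (0.0145), and in E14.5 R3 without Gata1s E14.5 R1/2 replicate 1 (0.0454). With libraries of prefix MS only, 1 of them wild type per group, it passed in all combinations. In E14.5 R1/2 the log2 was then -1.98, and 0.40 (not called) with JC only, 1 library of each genotype.

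Embryonic globins, which belong to the primitive red cells of the yolk sac, were higher in Gata1s R1/2. At E14.5, Hbb-y rose from 1020 ± 144 to 45200 ± 47600 (5.06 ± 1.01, adjusted p = 0.00418), Hba-x from 227 ± 8.59 to 8790 ± 7150 (5.09 ± 0.91, 0.00185) and Hbb-bh1 from 434 ± 415 to 1870 ± 688 (2.39 ± 0.58, 0.0141). At E12.5, Hba-x rose from 2720 ± 3170 to 15600 ± 9280 (3.12 ± 0.86, 0.0314) and Hbb-bh1 from 1130 ± 597 to 5570 ± 2630 (2.27 ± 0.55, 0.0141), while Hbb-y was 9330 ± 10300 and 34300 ± 21400 (2.31, 0.165). In E12.5 R3, Hbb-y fell from 290000 ± 191000 to 16800 ± 12200 (-3.27 ± 1.08, 0.0264), with Hba-x at 62500 ± 43100 and 13300 ± 6860 (-1.40, 0.278) and Hbb-bh1 at 41400 ± 12100 and 44400 ± 8500 (-0.18, 0.841). No embryonic globin passed in E14.5 R3: Hbb-y was 16200 ± 20100 and 2690 ± 1200 (-0.98, 0.529), Hba-x 2350 ± 2530 and 2020 ± 1200 (0.77, 0.591), and Hbb-bh1 16600 ± 7070 and 34500 ± 16200 (0.80, 0.355). Over the 4 combinations Hba-x rose by 1.89 ± 0.49 (0.00507) and Hbb-bh1 by 1.32 ± 0.31 (0.00247), and Hbb-y was at 0.78 ± 0.54 (0.264).

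Hbb-bh2 had few counts, 26.2 ± 12.6 against 53.7 ± 11.9 in E12.5 R3 (0.55, adjusted p = 0.55) and 14.4 ± 6.34 against 35.2 ± 34.1 in E14.5 R3 (0.47, 0.631). In R1/2 it had 0.874 ± 0.604 against 4.25 ± 3.19 at E12.5 (1.32, 0.198) and 0.211 ± 0.298 against 2.54 ± 0.905 at E14.5 (1.40, 0.189). Its mean of 0.93 ± 0.33 (0.031) was lost without wild type E12.5 R1/2 replicate 2 (0.0691), E14.5 R1/2 replicate 2 (0.14) or E14.5 R3 replicate 2 (0.0597), or Gata1s E12.5 R3 replicate 1 (0.0655), E14.5 R1/2 replicate 1 (0.0584) or E14.5 R3 replicate 2 (0.079). In E12.5 R1/2, Hba-x did not pass without wild type replicate 2 (0.382) or Gata1s replicate 3 (0.0826) or 4 (0.0848), nor without the prefix term, with JC only, on the groups compared only, without a filter, with robust empirical Bayes or with either list as a covariate. Hbb-bh1 did not pass there without wild type replicate 2 (0.245). At E14.5 in R1/2, Hbb-bh1 did not pass without wild type replicate 1 (0.218) or Gata1s replicate 1 (0.0753). In E12.5 R3, Hbb-y did not pass without wild type replicate 1 (0.0556) or 3 (0.0675) or Gata1s replicate 2 (0.193). Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 had 8, 6, 12 and 1 reads over all libraries, which says little for genes with near-identical copies.

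**Figure D2:**
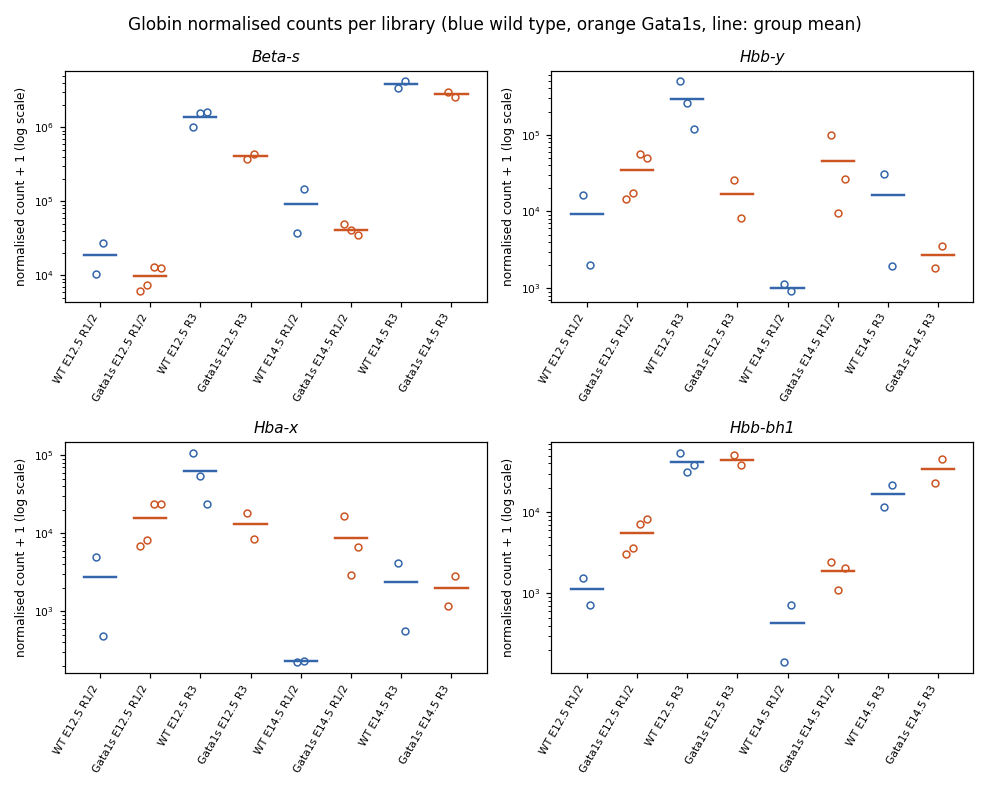
Normalised counts plus 1 on a log scale for 4 globins in each library, wild type in blue and Gata1s in orange. In E14.5 R1/2 the Hba-x means were 227 and 8790, and in E12.5 R3 the Beta-s means were 1390000 and 406000.

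Over the 4 combinations, with 9 wild type and 11 Gata1s libraries, the largest changes with 1 direction in all combinations were in single genes of varied function. Slc7a11, the cystine and glutamate exchanger, rose by 5.92 ± 0.25 log2 (limma adjusted p = 5.7e-11), the prolyl hydroxylase Egln3 by 4.87 ± 0.40 (7.98e-08), and the heat shock gene Hspb8 by 4.25 ± 0.35 (7.11e-08). Padi2, a peptidylarginine deiminase, fell by 5.54 ± 0.29 (6.21e-10), Mboat2 by 4.82 ± 0.27 (1.26e-09), and Il1rl1, the receptor of interleukin 33, by 4.78 ± 0.31 (4.68e-09). Ccnb1ip1 had no read in Gata1s libraries of 3 combinations. Against a floor of 3 reads per library it was at least 209-fold lower in E12.5 R1/2 (wild type mean 374), at least 31.4-fold lower in E12.5 R3 (119) and at least 8.5-fold lower in E14.5 R3 (81.4). In E14.5 R1/2 it had 502 ± 20.7 against 0.443 ± 0.767. Sizes of Slc7a11, Egln3, Hspb8, Il1rl1 and Eng in this mean depend partly on the pseudocount, as a group mean lay under that floor.

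Megakaryocyte and platelet genes rose together in this mean, with 21 of 25 measured higher, 1 lower and 3 not passing, a median of 1.63 and a camera adjusted p of 2.9e-09. Itga2b, the platelet integrin chain, rose by 2.61 ± 0.15 (1.22e-09) and Nrgn by 2.06 ± 0.10 (2.19e-10). Genes of glycolysis and hypoxia rose as well, 22 higher and 3 lower of 26 (23 and 3 adjusted over the list alone; median 0.58, camera adjusted p = 2.9e-09), among them the glycolytic enzyme gene Aldoa by 1.35 ± 0.08 (1.58e-09) and Bnip3, a mitophagy receptor, by 1.55 ± 0.09 (1.07e-09). Of 25 cholesterol synthesis genes 17 were higher and 3 lower (median 0.43, camera adjusted p = 2.48e-06), with Idi1 at 1.04 ± 0.07 (5.88e-09) and Cyp51 at 1.01 ± 0.08 (3.8e-08). Adjusted p with an estimated correlation was 0.236 for the megakaryocyte and glycolysis lists and 0.507 for cholesterol synthesis.

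Erythroid genes fell in the same mean, largely through E12.5 R3. Heme synthesis had 15 of 20 members lower and 0 higher (16 lower adjusted over the list alone; median -0.34, camera adjusted p = 0.000239), including Hebp1, a heme-binding protein, by 1.00 ± 0.06 (limma adjusted p = 4.61e-09), and mitoferrin, Slc25a37, by 1.07 ± 0.10 (3.46e-07). Iron uptake and storage had 7 of 15 lower and 0 higher (median -0.28, 0.0226), with the transferrin receptor Tfrc at -0.70 ± 0.05 (1.26e-08) and the ferrireductase Steap3 at -0.79 ± 0.06 (2.03e-08). The red cell membrane list had 22 of 29 lower and 1 higher (median -0.46, 4.34e-06), with the adhesion molecule Icam4 at -1.23 ± 0.07 (9.08e-10) and Darc, the Duffy antigen, at -2.34 ± 0.13 (1.07e-09). Late erythroid maturation had 25 of 33 lower and 3 higher (26 and 3 adjusted over the list alone; median -0.47, 9.4e-05). Its members that rose included the carbonic anhydrase gene Car1 by 1.89 ± 0.07 (2.33e-11), and Alox15, a lipoxygenase of reticulocytes, by 2.45 ± 0.23 (4e-07). Adjusted p with an estimated correlation was 0.667 for heme synthesis and 0.712 for late maturation, and no call of these functional lists in any genotype comparison held with an estimated correlation.

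Cell cycle lists were lower by small amounts. S phase genes had 22 of 39 lower and 0 higher (25 adjusted over the list alone; median -0.15, camera adjusted p = 0.000282), with cyclin E1, Ccne1, at -0.83 ± 0.06 (1.83e-08) and E2f1 at -0.27 ± 0.04 (2.37e-05). G2 and M phase genes had 19 of 38 lower and 0 higher (median -0.15, 0.00381; adjusted p = 0.749 with an estimated correlation), with Ube2c at -0.96 ± 0.11 (2.16e-06) and Cks2 at -0.28 ± 0.04 (3.49e-05). The G2 and M call was lost without wild type E14.5 R3 replicate 2 (0.073), and quantile normalisation ended those of S phase (0.221), G2 and M phase (0.216) and iron uptake (0.221).

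The other lists did not pass in the mean over the 4 combinations. Erythroid transcription factors had 3 of 20 higher and 10 lower (camera adjusted p = 0.0718; 0.00701 without wild type E12.5 R1/2 replicate 2). Embryonic globins had 3 of 4 higher (0.101) and neutrophil and monocyte genes 4 of 26 higher and 1 lower (0.0605). Among interferon-stimulated genes 9 of 24 were higher and 4 lower (0.114; 0.0419 without wild type E14.5 R3 replicate 2). Stem and progenitor genes had 7 of 18 higher and 3 lower (0.388), macrophage genes 2 of 16 higher and 5 lower (0.388), immediate early genes 0 of 17 higher and 3 lower (0.439), and sex-linked genes 2 of 5 higher (0.472). The neutrophil and monocyte list passed without Gata1s E12.5 R1/2 replicate 2 (0.019), E12.5 R3 replicate 2 (0.0292) or E14.5 R3 replicate 2 (0.0426), or wild type E12.5 R1/2 replicate 2 (0.00234) or E14.5 R1/2 replicate 1 (0.000218). Hepatoblast genes had 1 of 12 lower (0.743), polycomb and H3K27 demethylase genes 8 of 30 higher and 8 lower (0.994), and ribosomal protein genes 4 of 77 higher and 6 lower (0.876). Of CDK inhibitors and cell cycle exit genes 4 of 21 were higher and 9 lower (0.511), the higher ones including the cyclin Ccnd2 by 1.58 ± 0.12 (2.22e-08), and the inhibitor Cdkn1a by 1.84 ± 0.17 (2.48e-07). Median and mean log2 differences had opposite signs in erythropoietin signalling (6 of 19 higher and 5 lower, 0.472), p53 targets (6 of 29 and 4, 0.511), mast cell, basophil and eosinophil genes (2 of 10 and 2, 0.743) and endothelial genes (3 of 7 and 2, 0.994). The erythropoietin target Cish rose by 1.51 ± 0.12 (4.18e-08), and Eng, the endoglin gene, fell by 2.93 ± 0.22 (3.55e-08).

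Of 10720 genes tested, limma called 4859 in the mean over the 4 combinations, 2115 higher and 2744 lower, and edgeR 4607, with 4414 called by both in the same direction. All 4 single comparisons called 195 genes higher and 212 lower, against 0.63 and 1.1 if the comparisons were independent. This total of 407 was 205 without wild type E12.5 R1/2 replicate 1 and 174 without wild type E14.5 R1/2 replicate 2. Under upper-quartile scaling 55.5% of the calls in the mean were higher, against 43.5% as tested.

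**Figure D3:**
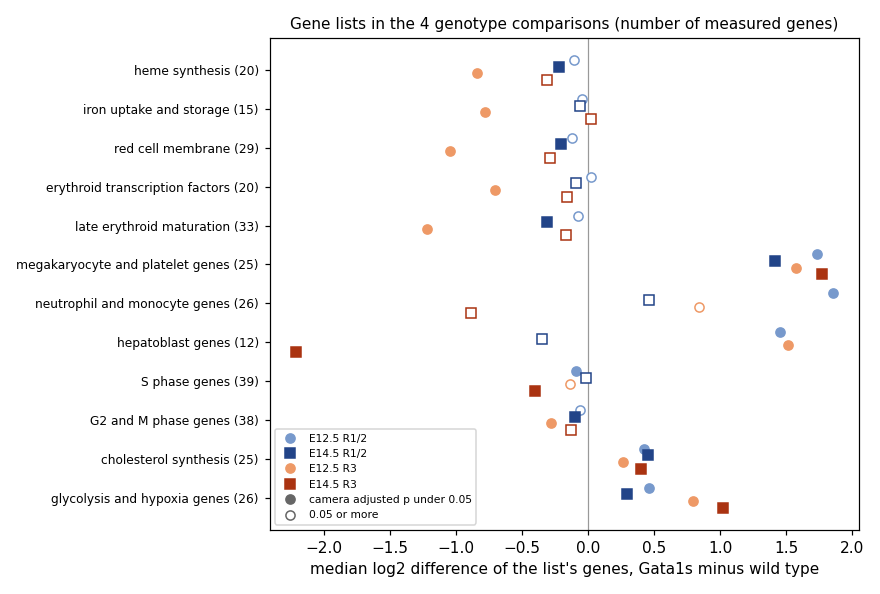
Median log2 difference, Gata1s minus wild type, of the measured genes of 12 lists in the 4 combinations of day and sort, with filled symbols where the camera adjusted p was under 0.05. Megakaryocyte and platelet genes had medians of 1.73 in E12.5 R1/2, 1.41 in E14.5 R1/2, 1.57 in E12.5 R3 and 1.77 in E14.5 R3. Late maturation genes had -1.22 in E12.5 R3, while the G2 and M phase list at E12.5 R3 (-0.28) changed direction under quantile normalisation.

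In E12.5 R1/2, with 2 wild type and 4 Gata1s libraries, Slc7a11 rose from 16.8 ± 7.21 to 316 ± 69 (4.19 ± 0.44, limma adjusted p = 1.66e-05) and Hecw1 from 14.3 ± 1.88 to 161 ± 10.7 (3.40 ± 0.37, 2.33e-05). Chst15 fell by 5.10 ± 0.43 to 3.49 ± 1.83 (2.23e-06), and Acsl6 from 112 ± 1.68 to 3.52 ± 1.45 (-4.71 ± 0.59, 8.22e-05). Il1rl1 fell from 148 ± 52.2 to 5.31 ± 2.81 (-4.66 ± 0.54, 4.18e-05) and Eng from 159 ± 57.6 to 8.73 ± 5.28 (-4.17 ± 0.40, 6.29e-06). The red cell genes Car1 and Darc moved apart, Car1 from 490 ± 60.6 to 2560 ± 233 (2.38 ± 0.13, 1.49e-08) and Darc from 61.8 ± 10.2 to 13.2 ± 3.99 (-2.18 ± 0.23, 1.69e-05). For each of these genes no wild type library overlapped the Gata1s libraries.

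Of 25 megakaryocyte and platelet genes 13 were higher and 1 lower (17 and 1 adjusted over the list alone; median 1.73, camera adjusted p = 3.95e-11), with Nrgn at 1.89 ± 0.17 (4.33e-06) and Plek at 3.11 ± 0.37 (4.8e-05). Cholesterol synthesis had 13 of 25 higher (17 and 1 lower adjusted over the list alone; median 0.42, 9.82e-11), including the squalene synthase Fdft1 by 0.93 ± 0.08 (4.33e-06) and Fdps by 0.89 ± 0.10 (4.8e-05). Glycolysis and hypoxia genes had 13 of 26 higher and 1 lower (14 and 1 adjusted over the list alone; median 0.46, 5.99e-09), including the phosphofructokinase Pfkp by 1.72 ± 0.20 (4.8e-05) and Bnip3 by 1.05 ± 0.15 (0.00028). Adjusted p with an estimated correlation was 0.157 for the megakaryocyte list and 0.17 for the cholesterol and glycolysis lists.

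The E12.5 R1/2 lists named in this paragraph depended on single libraries or on the prefix term for the library names. Embryonic globins had 2 of 4 higher (4 adjusted over the list alone; median 2.29, camera adjusted p = 0.00671; adjusted p = 0.303 with an estimated correlation), and 0.117 without wild type replicate 2. Neutrophil and monocyte genes had 5 of 26 higher (9 and 1 lower adjusted over the list alone; median 1.85, 2.41e-07; adjusted p = 0.533 with an estimated correlation), and 0.092 without wild type replicate 1. Their members Ltf (3.29 ± 0.63) and Ngp (3.59 ± 0.74), of neutrophil granules, then had adjusted p of 0.121 and 0.203. Hepatoblast genes, markers of the liver's own cells, had 3 of 12 higher (5 adjusted over the list alone; median 1.45, 0.000845; adjusted p = 0.303 with an estimated correlation), and 0.0575 without the prefix term. Alb (1.77 ± 0.46, 0.0229) did not pass without wild type replicate 1 (0.0685) or 2 (0.2) or Gata1s replicate 3 (0.0571) or 4 (0.0567), nor Trf (1.39 ± 0.36, 0.0211) without wild type replicate 1 (0.105) or 2 (0.134) or Gata1s replicate 1 (0.0649).

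S phase genes had 3 of 39 lower in E12.5 R1/2 (median -0.09, camera adjusted p = 0.0121; adjusted p = 0.834 with an estimated correlation), and 0.463 without wild type replicate 1. Ccne1 fell by 0.52 ± 0.11 (0.00432) and the primase gene Prim1 by 0.27 ± 0.06 (0.00531), and neither passed without that library (0.0905 and 0.0613). Erythropoietin signalling passed with 6 of 19 higher (median -0.01, mean 0.42, 0.0378; adjusted p = 0.17 with an estimated correlation), led by Cish at 1.79 ± 0.21 (4.33e-05) and the cytokine Osm at 2.08 ± 0.34 (0.000797). It did not pass without wild type replicate 2 (0.129), Gata1s replicate 3 (0.0642), or wild type E14.5 R3 replicate 1 or 2 (0.0649 each). limma called 531 genes higher and 493 lower in E12.5 R1/2, 1024 in all, and edgeR 1538, with 1019 called by both. Without wild type replicate 1 limma called 460.

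In E14.5 R1/2, with 2 wild type and 3 Gata1s libraries, Slc7a11 rose from 6.47 ± 5.73 to 419 ± 93.6 (6.14 ± 0.46, limma adjusted p = 5.58e-07) and Prkcq from 19.8 ± 2.37 to 291 ± 40.8 (3.77 ± 0.26, 2.47e-07). The fatty acid transporter Cd36 fell from 178 ± 159 to 3.39 ± 1.6 (-5.10 ± 0.52, 1.33e-05) and Mboat2 by 5.21 ± 0.51 to 6.16 ± 1.98 (8.93e-06). Eng fell from 468 ± 22.6 to 19.6 ± 5.08 (-4.43 ± 0.42, 7.83e-06). Car1 rose from 598 ± 156 to 3550 ± 178 (2.56 ± 0.14, 1.31e-08), Cish from 42 ± 0.428 to 171 ± 43.7 (1.95 ± 0.22, 2.6e-05), and Darc fell from 128 ± 83.3 to 22.2 ± 2.82 (-2.41 ± 0.24, 1.3e-05).

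Megakaryocyte and platelet genes had 13 of 25 higher and 1 lower (15 and 1 adjusted over the list alone; median 1.41, camera adjusted p = 7.9e-12; adjusted p = 0.13 with an estimated correlation), with Itga2b at 2.89 ± 0.27 (7.83e-06) and Nrgn at 2.66 ± 0.18 (2.01e-07). Embryonic globins had 3 of 4 higher (4 adjusted over the list alone; median 3.72, 0.00084; adjusted p = 0.346 with an estimated correlation). Cholesterol synthesis had 13 of 25 higher and 1 lower (14 and 2 adjusted over the list alone; median 0.45, 1.87e-07; adjusted p = 0.346 with an estimated correlation), with Fdft1 at 0.85 ± 0.09 (1.65e-05) and Fdps at 0.80 ± 0.11 (0.000206). Glycolysis and hypoxia genes had 8 of 26 higher and 2 lower (12 and 2 adjusted over the list alone; median 0.29, 3.66e-05; adjusted p = 0.449 with an estimated correlation). The phosphofructokinase of blood platelets and other cells, Pfkp, rose by 1.91 ± 0.21 (2.6e-05), and Pfkm, the muscle isoform that red cells also use, fell by 0.85 ± 0.11 (0.000145). Immediate early genes had 2 of 17 lower (5 adjusted over the list alone; median -0.93, 0.000888; adjusted p = 0.671 with an estimated correlation), with Junb at -1.04 ± 0.19 (0.00177) and Btg2 at -0.66 ± 0.18 (0.0309). Btg2 did not pass without wild type replicate 2 (0.461) or Gata1s replicate 1 (0.0718) or 3 (0.107).

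Erythroid lists were lower in E14.5 R1/2 by amounts that rested on wild type replicate 2, a library with 5.87% of its values in the ribosomal RNA gene Rn45s. Heme synthesis had 2 of 20 lower (5 lower and 1 higher adjusted over the list alone; median -0.22, camera adjusted p = 0.0347; 0.746 without that library, 0.101 and 0.137 without Gata1s replicates 2 and 3). The red cell membrane list had 8 of 29 lower (12 adjusted over the list alone; median -0.21, 0.00084; 0.242 without it). Late maturation had 7 of 33 lower and 2 higher (11 and 3 adjusted over the list alone; median -0.31, 0.0125; 0.935 without it, 0.0843 and 0.0934 without Gata1s replicates 2 and 3). For all 3 lists, adjusted p = 0.833 with an estimated correlation. Tfrc fell by 0.68 ± 0.09 (0.000152) and Slc25a37 by 1.24 ± 0.19 (0.000428), but Slc25a37 did not pass without the prefix term or on the groups compared only. Hebp1 (-0.63 ± 0.12, 0.00252) and Ube2l6 (-1.46 ± 0.28, 0.00306), did not pass without that library (0.114 and 0.138).

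G2 and M phase genes had 2 of 38 lower in E14.5 R1/2 (1 adjusted over the list alone; median -0.10, camera adjusted p = 0.0156; adjusted p = 0.833 with an estimated correlation), and did not pass without Gata1s replicate 2 (0.0622) or 3 (0.0716) or wild type replicate 1 (0.0634). Of these, the spindle protein gene Prc1 (-0.48 ± 0.10, 0.00483) did not pass without wild type replicate 2 (0.15). Ube2c (-0.69 ± 0.20, 0.0374) did not pass without wild type replicate 1 (0.0867) or 2 (0.311), Gata1s replicate 2 (0.109) or 3 (0.122), or Gata1s E12.5 R3 replicate 1 (0.0502) or 2 (0.0503). Neutrophil and monocyte genes had 0 of 26 called by limma (camera adjusted p = 0.204), and the list was higher without wild type replicate 1 (3.61e-11) and lower without replicate 2 (3.54e-07), whose mean log2 values over the list were 8.2 and 4.37 against 6.51 to 6.81 in Gata1s. Hepatoblast genes had 0 of 12 called (0.519). limma called 536 genes higher and 550 lower in E14.5 R1/2, 1086 in all, and edgeR 1460, with 1076 called by both. Without wild type replicate 2 limma called 310, and without Gata1s replicate 2 or 3 it called 681 or 699.

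R1/2 changes were shared between the days. Both days called 351 genes higher (27 if independent) and 345 lower (25), with 0 in opposite directions and a correlation of 0.80 of log2 differences across genes, which are not independent replicates. The test of the difference between days called 1 gene by limma (269 at an unadjusted p under 0.05), 2 by edgeR and 18 by DESeq2. That gene, Gm8615, a predicted gene named after its values were seen, had no read in wild type R1/2 at E14.5 and a mean of 41.9 in Gata1s (adjusted p = 0.0377), so the size depends on the pseudocount, and none was called with a pseudocount of 5. Leaving out single libraries gave 0 to 4 genes. Hepatoblast genes differed between the days (median -1.59, camera adjusted p = 2.8e-09). Immediate early genes (-0.83, 1.25e-06) and sex-linked genes (0.78, 0.000206) also passed, but not without wild type E12.5 R1/2 replicate 1 (0.179 and 0.0686). Neutrophil and monocyte genes (-1.34, 3e-07) did not pass without that library (0.879) and turned direction without wild type E14.5 R1/2 replicate 1 (0.0553). Late maturation, red cell membrane, glycolysis, G2 and M phase, S phase and ribosomal protein genes passed with medians of -0.20 to 0.06, and each lost its call or turned direction without at least 2 single libraries. With an estimated correlation the adjusted p of these lists ran from 0.121 to 0.744.

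In E12.5 R3, with 3 wild type and 2 Gata1s libraries, genes of the maturing red cell fell and genes of several other kinds rose. Trove2 rose from 48.6 ± 2.87 to 1330 ± 32.2 (4.65 ± 0.20, limma adjusted p = 5.19e-10), and Ahnak from 17.6 ± 2.13 to 522 ± 33.7 (4.71 ± 0.32, 7.11e-08). Cpne7 rose from 16.5 ± 5.95 to 472 ± 13.4 (4.52 ± 0.27, 1.8e-08) and Egln3 from 3.05 ± 1.24, too few reads for a fold, to 203 ± 115 (3.31e-05). Padi2 fell from 1870 ± 881 to 9.4 ± 0.28 (-7.58 ± 0.57, 1.93e-07) and cathepsin E, Ctse, from 12700 ± 6370 to 284 ± 23.2 (-5.58 ± 0.27, 1.27e-09). Fras1 had 268 ± 88.2 in wild type and no read in Gata1s, at least 70.8-fold lower against the floor of 3 reads per library. Phlda3, a p53 target, fell from 435 ± 318 to 11.8 ± 1.19 (-4.89 ± 0.46, 1.25e-06) and the survival gene Bcl2l1 from 12700 ± 3600 to 3120 ± 66.8 (-2.33 ± 0.26, 6.14e-06). Ccnd2 rose from 294 ± 41.9 to 1870 ± 229 (2.81 ± 0.23, 4e-07).

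Every erythroid list fell in E12.5 R3, where Rn45s also differed (0.618 to 0.724% of values in wild type, 2.09 and 2.68% in Gata1s). Late maturation had 30 of 33 lower and 2 higher (median -1.22, camera adjusted p = 4.41e-12), including Fbxo30 by 1.63 ± 0.13 (limma adjusted p = 4.09e-07) and the amino acid transporter Slc43a1 by 1.36 ± 0.13 (1.48e-06). The red cell membrane list had 26 of 29 lower (27 adjusted over the list alone; median -1.05, 4.41e-12), including Mpp1 by 2.37 ± 0.18 (2.18e-07) and Icam4 by 1.93 ± 0.13 (7.11e-08). Heme synthesis had 17 of 20 lower (18 adjusted over the list alone; median -0.84, 6.12e-07), with Hebp1 at -1.31 ± 0.13 (1.71e-06) and Slc25a37 at -1.54 ± 0.20 (2.37e-05). Iron uptake and storage had 11 of 15 lower (11 lower and 1 higher adjusted over the list alone; median -0.78, 4.36e-05), with Steap3 at -1.36 ± 0.11 (5.12e-07) and Tfrc at -1.04 ± 0.10 (1.24e-06). Erythroid transcription factors had 15 of 20 lower and 1 higher (16 and 1 adjusted over the list alone; median -0.71, 8.19e-06), with the erythroid master regulator Klf1 at -1.11 ± 0.12 (3.65e-06) and E2f2 at -1.73 ± 0.17 (2.5e-06). Adjusted p was 0.361 with an estimated correlation for heme synthesis and 0.344 for the other erythroid lists. Quantile normalisation ended the calls of the iron list (0.117) and of Tfrc, and that of Slc25a37 ended without the prefix term.

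Megakaryocyte and platelet genes had 11 of 25 higher and 1 lower in E12.5 R3 (13 and 1 adjusted over the list alone; median 1.57, camera adjusted p = 3.93e-05), with the thrombin receptor gene F2rl2 at 3.66 ± 0.47 (2.16e-05) and Nrgn at 1.44 ± 0.19 (3.51e-05). Glycolysis and hypoxia genes had 15 of 26 higher and 3 lower (18 and 3 adjusted over the list alone; median 0.79, 8.5e-06), with the glucose transporter Slc2a3 at 1.33 ± 0.14 (3.44e-06) and Aldoa at 1.47 ± 0.15 (3.75e-06). Cholesterol synthesis had 12 of 25 higher and 1 lower (median 0.26, 0.000431), with Idi1 at 1.56 ± 0.13 (6.25e-07) and Cyp51 at 1.28 ± 0.15 (1.34e-05). Adjusted p with an estimated correlation was 0.344 for the first pair of lists and 0.414 for cholesterol synthesis. G2 and M phase genes had 16 of 38 lower and 1 higher (17 and 1 adjusted over the list alone; median -0.28, 0.000967; adjusted p = 0.664 with an estimated correlation), a direction that turned under quantile normalisation (0.706), and the list did not pass without wild type replicate 3 (0.144). Among them Ube2c fell by 1.77 ± 0.21 (1.27e-05) and the cyclin Ccna2 by 0.59 ± 0.09 (0.000159), of which Ccna2 did not pass under quantile normalisation.

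Hepatoblast genes had 5 of 12 higher beside these erythroid lists in E12.5 R3 (median 1.51, camera adjusted p = 0.00758; adjusted p = 0.414 with an estimated correlation). The list did not pass without Gata1s replicate 1 (0.126), without the prefix term (0.763) or with libraries of prefix MS only (0.11). Trf (1.48 ± 0.40, 0.00897) did not pass without Gata1s replicate 1 (0.166), nor Itih2 (65.2 ± 20.5 and 96.5 ± 37.6; 1.89 ± 0.60, 0.0217) without Gata1s replicate 1 (0.163) or wild type replicate 1 (0.0544) or 2 (0.0507). limma called 3849 genes in E12.5 R3, 1527 higher and 2322 lower, and edgeR 3820, with 3509 called by both. Of these calls 39.7% were higher, against 61.3% under upper-quartile scaling and 54.4% under quantile normalisation.

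Genes that separate R3 from R1/2 in wild type of the other day were shifted in E12.5 R3. Of 2496 genes higher in wild type R3 at E14.5, 1419 were lower and 79 higher in Gata1s (median -0.50, camera p = 1.11e-35; p = 0.0209 with an estimated correlation). Of 3026 genes lower in wild type R3, 810 were higher and 129 lower (median 0.34, p = 2.19e-18; p = 0.0892 with an estimated correlation). In the other combinations the same test gave p = 0.228 and 0.216 in E12.5 R1/2, 0.0187 and 0.344 in E14.5 R1/2 (p = 0.627 with an estimated correlation for the first), and 0.492 and 0.35 in E14.5 R3. These results moved with single libraries. In E12.5 R1/2 both lists shifted as in E12.5 R3 without wild type replicate 2 and the opposite way without wild type replicate 1. There the second list also passed without wild type E14.5 R1/2 replicate 2. In E14.5 R3 they shifted as in E12.5 R3 without wild type replicate 1 (0.00323 and 9.16e-05) and the opposite way without replicate 2 (0.024 and 0.0112). The first list did not pass in E14.5 R1/2 without wild type replicate 2 (0.334) or Gata1s replicate 2 (0.0646) or 3 (0.154), and the second passed without Gata1s replicate 1 (0.0106).

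The genotype difference in R3 was tested against that in R1/2 at E12.5. It was lower in R3 for Mpp1 (-2.13 ± 0.24, limma adjusted p = 0.000103), the skeleton protein gene Epb4.1 (-1.89 ± 0.27, 0.000442), Cat, the catalase gene (-1.73 ± 0.24, 0.00037), Fbxo30 (-1.30 ± 0.18, 0.00037), the kinase Pim1 (-1.80 ± 0.20, 6.94e-05) and the transcription factor Nfe2 (0.00016). Fbxo30 did not pass without the prefix term or on the groups compared only. Trove2 rose by 3.53 ± 0.27 (2.59e-06) and Ccnd2 by 1.91 ± 0.31 (0.000997) more in R3. Hbb-y (-5.58 ± 1.44, 0.0162) and Hba-x (-4.52 ± 1.30, 0.0276) differed too. Hbb-y did not pass without Gata1s R3 replicate 2 (0.0835) or wild type R1/2 replicate 2 (0.0726), and Hba-x did not pass without Gata1s R1/2 replicate 3 (0.0614) or 4 (0.064), Gata1s R3 replicate 2 (0.114), wild type R1/2 replicate 2 (0.126) or wild type R3 replicate 3 (0.0517). Fras1, at 0 reads in Gata1s R3, also passed (0.000208), with a size that depends on the pseudocount.

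Late maturation had 27 of 33 lower in this difference between sorts (30 adjusted over the list alone; median -1.09, camera adjusted p = 3.68e-16) and red cell membrane 22 of 29 (26 adjusted over the list alone; -0.88, 2.62e-12). Erythroid transcription factors had 15 of 20 lower (16 lower and 1 higher adjusted over the list alone; -0.72, 5.24e-08). Heme synthesis had 12 of 20 lower (15 adjusted over the list alone; -0.66, 1.68e-06) and iron uptake 8 of 15 (10 lower and 1 higher adjusted over the list alone; -0.41, 0.000162). Their adjusted p was 0.254 to 0.363 with an estimated correlation. G2 and M phase genes had 4 of 38 lower and 1 higher (8 and 1 adjusted over the list alone; -0.26, 0.00263; adjusted p = 0.893 with an estimated correlation), with 0.188 without wild type R3 replicate 3 and the opposite direction under quantile normalisation (0.492). That scaling also ended the calls of heme synthesis (0.12) and iron uptake (0.492). limma called 1652 genes, 452 higher and 1200 lower, and edgeR 1748. The count was 943 without wild type R3 replicate 3, 1040 and 1020 without Gata1s R3 replicates 1 and 2, and 1001 without wild type R1/2 replicate 2. As tested 27.4% of calls were higher against 53.5% under upper-quartile scaling and 56.1% under quantile normalisation.

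In E14.5 R3, with 2 libraries of each genotype, Slc7a11 rose from 8.98 ± 6.02 to 4500 ± 765 (limma adjusted p = 3.4e-09) and Prune2 from 5.67 ± 1.34 to 1080 ± 15.6 (1.13e-08), both from too few reads for a fold, and Trove2 from 33.9 ± 1.19 to 5900 ± 979 (7.32 ± 0.21, 1.65e-12). Padi2 fell from 2070 ± 1220 to 13.6 ± 3.61 (-7.17 ± 0.61, 2.26e-07) and Phlda3 from 470 ± 23.4 to 7.73 ± 0.5 (1.95e-07), too few reads for a fold. Fras1 had 379 ± 25.5 in wild type and no read in Gata1s, at least 39.6-fold lower against the floor of 3 reads per library. The lipid transfer protein gene Stard10 had 531 ± 83.7 and 1.84 ± 2.61 (2.04e-08), also too few. The demethylase gene Kdm6b rose from 138 ± 15.1 to 1200 ± 106 (3.19 ± 0.19, 7.2e-09) and the polycomb member Phc1 from 112 ± 8.61 to 358 ± 11.3 (1.65 ± 0.16, 7.94e-07). Cish rose from 711 ± 29.7 to 3330 ± 277 (2.15 ± 0.25, 5.75e-06). Ccnd2 rose from 176 ± 102 to 670 ± 90.3 (2.15 ± 0.24, 5e-06) and Cdkn1a from 107 ± 1.93 to 589 ± 235 (2.38 ± 0.35, 6.83e-05).

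Glycolysis and hypoxia genes had 18 of 26 higher and 1 lower in E14.5 R3 (20 and 1 adjusted over the list alone; median 1.02, camera adjusted p = 9.3e-08), with Slc2a3 rising from 621 ± 50.4 to 7590 ± 401 (3.59 ± 0.15, 6.97e-11) and Bnip3 from 405 ± 14.3 to 3230 ± 133 (3.05 ± 0.18, 5.33e-09). Megakaryocyte and platelet genes had 15 of 25 higher and 1 lower (17 and 1 adjusted over the list alone; median 1.77, 7.68e-06), with Itga2b at 3.47 ± 0.31 (3.9e-07) and Nrgn at 2.24 ± 0.21 (5.4e-07). Adjusted p was 0.491 with an estimated correlation for both lists. S phase genes had 30 of 39 lower (32 adjusted over the list alone; median -0.40, 2.91e-07; adjusted p = 0.731 with an estimated correlation), with Ccne1 at -1.57 ± 0.13 (1.27e-07) and E2f1 at -0.68 ± 0.08 (7.09e-06). Cholesterol synthesis had 12 of 25 higher and 3 lower (median 0.40, 0.00915; adjusted p = 0.885 with an estimated correlation), and did not pass without wild type replicate 2 (0.115).

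Erythroid lists had smaller differences in E14.5 R3. The red cell membrane list had 8 of 29 lower (median -0.29) with a camera adjusted p of 0.05, at the threshold, and of 0.482 without wild type replicate 2 and 0.131 without Gata1s replicate 1, and 12 other libraries left out singly gave 0.0505 to 0.0714. The other erythroid lists did not pass, with heme synthesis at 6 of 20 lower (0.0856), erythroid transcription factors 4 of 20 higher and 8 lower (0.707), and late maturation 7 of 33 higher and 7 lower (0.791). Hebp1 fell by 1.38 ± 0.13 (limma adjusted p = 9.98e-07) and Icam4 by 1.03 ± 0.14 (3.06e-05), and Car1 rose by 1.22 ± 0.15 (1.52e-05). Hepatoblast genes had 7 of 12 lower (9 adjusted over the list alone; median -2.21, camera adjusted p = 0.00915; adjusted p = 0.731 with an estimated correlation). Their mean log2 values were 7.13 and 4.13 in wild type and 2.33 and 2.78 in Gata1s, and the list did not pass without wild type replicate 1 (0.0735) or with prefix MS only (0.14). Itih2 had 78.9 ± 84.9 and 1.35 ± 1.9 (0.000218) and Apob 115 ± 123 and 4.04 ± 5.71 (0.00311), too few reads in Gata1s for a fold. Macrophage genes had 6 of 16 lower (median -1.15, 0.0856) and G2 and M phase genes 10 of 38 lower (0.0856). Without wild type replicate 1 the heme and G2 and M lists passed (0.0355 and 0.00268). So did the heme list without wild type E12.5 R1/2 replicate 1 or 2 (0.039 each) and the G2 and M list without Gata1s replicate 2 (0.0383).

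limma called 4013 genes in E14.5 R3, 1797 higher and 2216 lower, and edgeR 3179, with 3110 called by both. In a test on simulated data with these group sizes, 42.8% of 320 limma calls in this comparison were false, and 21.7% of 212 among genes with a mean of at least 50, against 5.4% of 168 calls by edgeR, which recovered 73 and 86% of changes of log2 1 and 2 against 88 and 95% by limma. With only 100 genes changed by each amount, these shares do not carry over to the real counts.

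R3 changes differed between the days. Both days called 767 genes higher (256 if independent) and 1018 lower (480), 58 and 133 were called in opposite directions, and log2 differences correlated at 0.60 across genes. The test of the difference between days called 2468 genes, 1445 higher and 1023 lower at E14.5, and edgeR 2084. Late maturation had 27 of 33 higher (30 adjusted over the list alone; median 1.10, camera adjusted p = 6.78e-12), the red cell membrane list 18 of 29 (23 adjusted over the list alone; 0.74, 1.41e-07), and erythroid transcription factors 14 of 20 higher and 2 lower (17 and 3 adjusted over the list alone; 0.68, 0.000142). Fbxo30 differed by 1.80 ± 0.19 (limma adjusted p = 3.85e-05) and the autophagy kinase Ulk1 by 1.58 ± 0.20 (0.000137). Cbfa2t3 differed by 1.67 ± 0.28 (0.00073), Foxo3 by 1.40 ± 0.24 (0.000937) and Epb4.1 by 1.59 ± 0.28 (0.00107). Heme synthesis had 9 of 20 higher and 1 lower (10 and 1 adjusted over the list alone; 0.45, 0.00579) and iron uptake 9 of 15 higher and 1 lower (0.42, 0.00483). Adjusted p was 0.417 with an estimated correlation for these lists, except 0.568 for heme synthesis.

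Slc2a3 (2.25 ± 0.19, limma adjusted p = 6.65e-06), Kdm6b (2.50 ± 0.26, 3.75e-05) and Slc7a11 (0.00017) rose more in E14.5 R3 than in E12.5 R3. S phase genes had 16 of 39 lower (median -0.28, camera adjusted p = 2.09e-06), with the replication factor Rfc4 at -0.86 ± 0.12 (0.000248). Of the glycolysis and hypoxia list 7 of 26 were higher and 2 lower (8 and 2 adjusted over the list alone; 0.33, 0.0192). Hepatoblast genes had 9 of 12 lower (11 adjusted over the list alone; -3.66, 2.09e-06), with Alb at -3.80 ± 0.72 (0.00192) and Itih2 passing (0.000327). Adjusted p was 0.417 with an estimated correlation for hepatoblast and S phase genes and 0.502 for glycolysis. With the mean of the hepatoblast genes as a covariate, 12 genes were called and of the 11 named for this difference only Slc2a3 passed. Log2 values were then nearer 0 for Alb (-1.5) and Cbfa2t3 (0.73), but 2.06 for Fbxo30, 1.68 for Ulk1 and 2.16 for Kdm6b. Heme synthesis did not pass without wild type E14.5 R3 replicate 1 (0.0628) or under quantile normalisation (0.414). Glycolysis did not pass without Gata1s E14.5 R3 replicate 1 (0.0696) or wild type E14.5 R3 replicate 2 (0.135). Quantile normalisation also ended the calls of iron uptake (0.253) and glycolysis (0.498). Of the calls 58.5% were higher, against 43.9% under upper-quartile scaling and 43.7% under quantile normalisation.

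At E14.5 the genotype difference of R3 exceeded that of R1/2 in Ahnak (5.56 ± 0.45, limma adjusted p = 1.19e-06), Trove2 (5.54 ± 0.28, 8.24e-09), the protocadherin Pcdh7 (3.27e-08, few reads in wild type R3), Slc2a3 (3.73 ± 0.19, 8.24e-09), Kdm6b (2.89 ± 0.26, 2.61e-06) and Junb (2.20 ± 0.28, 7.33e-05). It was lower in R3 for Ccne1 (-1.07 ± 0.17, 0.00041), Phlda3 (0.000239) and Stard10 (0.000247), both with few reads in Gata1s R3, and Hbb-y (-6.05 ± 1.51, 0.0125), of which Hbb-y did not pass without wild type R1/2 replicate 1 (0.0643). Glycolysis and hypoxia genes had 10 of 26 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.66, camera adjusted p = 4.26e-05) and S phase genes 11 of 39 lower (21 adjusted over the list alone; -0.33, 1.7e-07). Hepatoblast genes had 4 of 12 lower (5 adjusted over the list alone; -1.87, 0.0347), but 0.125 without wild type R1/2 replicate 1 and 0.277 without wild type R3 replicate 1. Immediate early genes had 2 of 17 higher (1.14, 0.0347), but 0.148 and 0.0538 without Gata1s R1/2 replicates 2 and 3, 0.156 without Gata1s R3 replicate 2, 0.0562 without wild type R1/2 replicate 2 and 0.277 without wild type R3 replicate 1. Adjusted p was 0.999 with an estimated correlation for these 4 lists. limma called 1687 genes, 764 higher and 923 lower, and edgeR 1379.

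Wild type cells changed widely from R1/2 to R3, over both days. Genes of hemoglobin and iron rose, Alas2, the erythroid enzyme that starts heme synthesis, by 6.10 ± 0.26 (limma adjusted p = 1.37e-12), Beta-s by 6.07 ± 0.27 (3.27e-12) and Slc25a37 by 5.37 ± 0.14 (9.85e-15). So did the glycophorin Gypc by 3.19 ± 0.07 (8.33e-15), Nfe2 by 4.08 ± 0.10 (8.33e-15) and Bcl2l1 by 5.25 ± 0.18 (1.34e-13). The stem cell factor receptor Kit fell by 5.31 ± 0.18 (1.08e-13), the progenitor factor Myb by 4.60 ± 0.16 (1.2e-13) and Acsl6 also fell (2.06e-09), to too few reads for a fold. Late maturation had 33 of 33 higher (median 3.52, camera adjusted p = 2.82e-12), and red cell membrane 28 of 29 (3.84, 9.83e-12). Heme synthesis had 19 of 20 higher and 1 lower (3.21, 8e-08), iron uptake 11 of 15 with 1 lower (0.72, 0.00273), and erythroid transcription factors 14 of 20 with 3 lower (1.93, 0.00159). Stem and progenitor genes had 13 of 18 lower and 1 higher (-2.16, 0.00506).

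Cell cycle genes were higher in wild type R3 too. G2 and M phase genes had 38 of 38 higher (median 1.74, camera adjusted p = 3.16e-12), with Ccna2 at 1.99 ± 0.07 (limma adjusted p = 9.58e-14). S phase genes had 36 of 39 higher and 1 lower (0.81, 2.98e-08), with E2f1 at 1.86 ± 0.05 (2.24e-14). CDK inhibitors and cell cycle exit genes had 16 of 21 higher and 4 lower (1.62, 0.00506), with Ccnd3 at 3.38 ± 0.07 (6.48e-15) and Mxd1, an antagonist of Myc, at 4.82 ± 0.11 (8.33e-15). Macrophage genes had 13 of 16 higher (2.70, 0.00602), including the cathepsin Ctsb by 4.03 ± 0.13 (6.21e-14). The hepatoblast gene Alb rose by 3.37 ± 0.36 (2.09e-07). Ribosomal protein genes had 43 of 77 higher and 10 lower (43 and 9 adjusted over the list alone; 0.18, 0.0129), a direction that turned under quantile normalisation (1.36e-12) and upper-quartile scaling (0.757), and did not pass without wild type E12.5 R1/2 replicate 1 (0.0751) or E14.5 R1/2 replicate 1 (0.106). Adjusted p was 0.857 with an estimated correlation for ribosomal genes and 0.298 for the other called lists, and quantile normalisation ended the calls of S phase (0.185) and iron uptake (0.242). limma called 9095 genes, 4298 higher and 4797 lower, and edgeR 9102. The median of all genes was -0.43 under upper-quartile scaling, where 35.4% of calls were higher against 47.3%.

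Gata1s cells also changed widely from R1/2 to R3. Slc25a37 rose by 5.33 ± 0.14 (limma adjusted p = 3.02e-14), Beta-s by 5.47 ± 0.27 (1.03e-11), Nfe2 by 3.19 ± 0.09 (6.13e-14), Mxd1 by 4.76 ± 0.11 (2.17e-14) and Fn3k (1.01e-13, few reads in E12.5 R1/2). Kit fell by 5.18 ± 0.17 (1.83e-13), Myb by 4.35 ± 0.15 (2.6e-13), Sh2d4a (6.1e-09, few reads in R3), Egfl7 by 3.09 ± 0.13 (1.45e-12) and Nrgn by 1.96 ± 0.13 (5.64e-10). Late maturation had 32 of 33 higher and 1 lower (median 3.00, camera adjusted p = 1.29e-11), and red cell membrane 28 of 29 and 1 (3.04, 6.03e-11). Heme synthesis had 19 of 20 higher and 1 lower (2.74, 1.81e-07), and iron uptake 10 of 15 and 2 (0.80, 0.021). Erythroid transcription factors had 14 of 20 higher and 5 lower (1.45, 0.00703) and G2 and M phase genes 38 of 38 (1.54, 1.11e-11). S phase genes had 34 of 39 higher and 1 lower (0.64, 5.35e-07), cell cycle exit genes 17 of 21 and 4 (2.03, 0.00169), and macrophage genes 13 of 16 (2.33, 0.0114). Ribosomal protein genes had 54 of 77 higher and 4 lower (0.25, 0.000462), a direction that turned under quantile normalisation (5.44e-10). Iron uptake did not pass under upper-quartile scaling (0.0529) or quantile normalisation (0.447), nor S phase genes under the latter (0.168). Stem and progenitor genes had 12 of 18 lower and 2 higher (-1.56, 0.0156; 0.0529 under upper-quartile scaling). Adjusted p was 0.812 with an estimated correlation for ribosomal genes and 0.42 for the other called lists. limma called 8922 genes, 4243 higher and 4679 lower, and edgeR 8893, with a median of all genes of -0.334 under upper-quartile scaling and 38.1% of calls higher against 47.6%.

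In wild type, E14.5 differed from E12.5 in globins, maturation genes and markers of myeloid cells, over both sorts. Hba-x fell by 3.84 ± 0.68 (limma adjusted p = 0.000686) and Hbb-y by 3.65 ± 0.75 (0.00199), while Beta-s rose by 1.75 ± 0.27 (0.00028), Mpp1 by 1.34 ± 0.13 (1.4e-05), Fbxo30 by 0.88 ± 0.09 (2.54e-05), the exonuclease Isg20 by 3.48 ± 0.20 (1.12e-07) and Cd36 by 3.42 ± 0.38 (3.59e-05). The granule protease genes Ctsg (0.000765) and Elane (0.011) rose, from few reads in E12.5 R3, of which Elane did not pass without wild type E12.5 R1/2 replicate 1 (0.0555) or E14.5 R1/2 replicate 1 (0.084). Late maturation had 31 of 33 higher (32 adjusted over the list alone; median 0.86, camera adjusted p = 4.12e-19) and red cell membrane 29 of 29 (0.66, 2.06e-13). Heme synthesis had 15 of 20 higher (16 adjusted over the list alone; 0.48, 2.51e-07) and iron uptake 7 of 15 (0.15, 0.0132; 0.0578 without wild type E12.5 R1/2 replicate 2 and 0.933 under quantile normalisation). Erythroid transcription factors had 11 of 20 higher and 1 lower (13 and 1 adjusted over the list alone; 0.27, 0.00117; 0.26 under quantile normalisation), and G2 and M phase genes 31 of 38 (34 adjusted over the list alone; 0.30, 2.98e-10). Embryonic globins had 3 of 4 lower (-2.61, 0.0132).

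Neutrophil and monocyte genes had 21 of 26 higher at E14.5 in wild type (25 adjusted over the list alone; median 2.19, camera adjusted p = 2.51e-07). Their mean log2 values in R1/2 were 3.11 and 4.78 at E12.5 and 8.2 and 4.37 at E14.5, so the rise there rested largely on replicate 1, without which the list still passed over both sorts. In R3 they were 3.44 to 4.48 and 5.45 to 6.32. Macrophage genes had 7 of 16 higher (10 adjusted over the list alone; 1.13, 0.000854). Interferon-stimulated genes had 13 of 24 higher (14 adjusted over the list alone; 0.91, 2.82e-07), including Irf9 by 0.88 ± 0.11 (limma adjusted p = 4.67e-05). Immediate early genes had 7 of 17 higher (9 adjusted over the list alone; 0.74, 0.0042; 0.0616 without wild type E12.5 R1/2 replicate 1). Cell cycle exit genes had 10 of 21 higher and 2 lower (12 and 2 adjusted over the list alone; 0.36, 0.00389). Of 26 glycolysis and hypoxia genes 14 were lower and 2 higher (-0.29, 0.00498), including Pfkp, which fell by 0.96 ± 0.16 (0.000429). Megakaryocyte and sex-linked genes also passed, and each lost its call without at least 2 single libraries. With an estimated correlation, adjusted p was 0.0715 for interferon-stimulated genes and 0.273 to 0.492 for the other called lists. limma called 3452 genes, 1919 higher and 1533 lower, and edgeR 3398. limma called 2142 without wild type E12.5 R1/2 replicate 2 and 2157 without wild type E14.5 R3 replicate 2. Of these calls 55.6% were higher, against 36.5% under upper-quartile scaling and 40.5% under quantile normalisation.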

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

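The 8 tests of explanations below and in the last part were chosen after the results were seen, and the counts of other sample splits before.

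Differences of the genotype effect between days or sorts are listed here because the difference itself passed a test, and single libraries because they lay apart in a group of 4. Such a gap arises by chance in about 1 in 20 groups, and 2 of 50 tested groups had one: Bnip3 was 1330 in Gata1s E12.5 R1/2 replicate 2 against 792 to 834 in the others, and Steap3 2810 in replicate 1 against 2900 to 2910.

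The first pattern is the lower level of maturation genes in Gata1s R3 at E12.5. As the whole cause, R1/2 cells in R3 would need a median share of 56 and 54% in replicates 1 and 2 (436 genes, lower quartiles 42 and 40%). Genes high in wild type R1/2 gave 3.15 and 2.46% (223 genes, upper quartiles 9.3 and 7.7%). This excludes only a mix of average R1/2 cells. Camera p was 8.09e-38 with reads thinned to the shallowest library, and 2.5e-26 with the prefix term and without the only wild type MS library of this group, which exclude depth and a prefix effect shared by the groups as the whole cause. A slower maturation of Gata1s cells may remain as a hypothesis, beside their place within the R3 gate, a cause tied to their higher Rn45s share and a prefix effect confined to E12.5 R3, for which MS only (1.19e-44) leaves 1 wild type library and takes the spread from other groups. The difference between sorts called 1652 genes, with log2 values of Mpp1 -2.13, Epb4.1 -1.89, Nfe2 -1.50, Fbxo30 -1.30, Cat -1.73, Pim1 -1.80, Ccnd2 1.91, Trove2 3.53 and Fras1 -6.27, the last depending on the pseudocount.

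The second pattern is the higher embryonic globins in Gata1s R1/2. The ratio of Hbb-y to Hba-x was at most 1.57 in Gata1s R3 and 2.06 to 5.92 in Gata1s R1/2, but wild type sorts also lay apart at E12.5 (3.35 to 4.25 and 4.55 to 5.01), so it does not decide whether 1 kind of cell is the source. At E14.5 each Gata1s R1/2 library had 10.5 to 88.5 times the Hbb-y and Hba-x of the wild type library of its prefix, which excludes prefix as the whole cause there. For Hbb-bh1 and for E12.5 the ratios ran from 0.863, for Hbb-y in replicate 1, to 49.4, and wild type libraries differed by up to 10.4 times, so prefix stays open. Primitive cells or a changed expression in definitive cells could be behind the pattern, and the sorts differed for Hbb-y by -5.58 at E12.5 and -6.05 at E14.5, and for Hba-x by -4.52 at E12.5.

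The third pattern is the 407 genes changed in 1 direction in all 4 combinations. Sequence of another strain around Gata1 would put such genes near it. Of the 100 nearest tested genes 5 were among them against 3.81 by chance (1-sided Fisher's exact test, p = 0.333), no clear excess. An effect of the mutation remains as a hypothesis, and strain sequence elsewhere and changes secondary to other cells of the embryo were not tested.

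Chance is unlikely for the mean over the combinations (4859 calls, highest other split 2931, 100 splits drawn). So it is for R3 against R1/2 in Gata1s (8922, 7541, 100). In wild type the real split also led for the sorts (9095, 8530, 60 splits) and the days (3452, 3226, 60). Other splits came near there, so chance is not excluded.

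Between days the difference called 1 gene in R1/2 and 2468 in R3. In R3 the log2 values were Slc7a11 5.19, Slc2a3 2.25, Kdm6b 2.50, Fbxo30 1.80, Ulk1 1.58, Cbfa2t3 1.67, Foxo3 1.40, Epb4.1 1.59, Rfc4 -0.86, Alb -3.80 and Itih2 -5.67, with few reads behind Slc7a11 and Itih2. Between sorts at E14.5 it called 1687 genes, with Ahnak 5.56, Trove2 5.54, Pcdh7 5.10, Slc2a3 3.73, Gata2 3.60, Kdm6b 2.89, Junb 2.20, Ccne1 -1.07, Phlda3 -4.42 and Stard10 -4.68, with few reads behind Pcdh7, Phlda3 and Stard10.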

How the results depend on the processing

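Tests with voom, thinned reads, a mean of at least 50 in the groups compared, and the 2 list covariates were chosen after seeing the data. The cause of a move was not tested.

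Counts of called genes moved as follows, in the order E12.5 R1/2, E12.5 R3, E14.5 R1/2, E14.5 R3 where not named. With a 2-fold minimum limma called 387, 1223, 451 and 1326 genes and 822 in their mean. This minimum gave 872 for the days in R3, 525 and 642 for the sorts at E12.5 and E14.5, 5157 and 4766 for R3 against R1/2 in wild type and Gata1s, 487 for the days in wild type, and 161 genes in all 4 combinations. Other tools gave more calls in R1/2: edgeR 1538 at E12.5, DESeq2 1861 and 1760, and voom 2180 and 1925 at E12.5 and E14.5. Quantile normalisation gave 1553 and 1630 there. On the groups compared only, E14.5 R3 had 1037, the days in R3 657, the sorts at E14.5 531, the days in wild type 691, and all 4 combinations 218.

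With the hepatoblast score counts were 421 in E12.5 R1/2, 1883 in E12.5 R3, 1655 in E14.5 R3, 12 for the days in R3, 843 for the sorts at E14.5 and 119 in all 4. With the neutrophil score they were 576 in E12.5 R1/2 and 258 in all 4. Prefix MS only gave 1660 in E14.5 R1/2 and 2569 for the sorts at E12.5. Prefix JC only gave 241 in E14.5 R1/2 and 1375 for the days in wild type.

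For the days in R1/2 the count of 1 was 2 by edgeR, 18 by DESeq2, 3 by voom, 152 with MS only and 10 with JC only. It was 0 with a pseudocount of 5, no filter, a mean of at least 50 overall or in the groups compared, quantile normalisation, no prefix term, the replicate block, the groups compared only, thinned reads, and either score.

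Pairs of sorts by consecutive library names were not tested. Deviations of same-numbered libraries correlated at a median of 0.04 (17 of 59 pairs over 0.1, 9 of 20 libraries best with their own number). With these numbers as a block and the prefix term, counts were 484 in E12.5 R1/2, 1758 in E12.5 R3, 1417 for the days in R3, 70 and 1068 for the sorts at E12.5 and E14.5, and 194 in all 4 combinations.

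The maturation test in E12.5 R1/2, for genes higher and lower in wild type R3, gave p of 2.95e-05 and 7.79e-06 with JC only. Its direction turned with MS only (0.00482 and 0.0441), for the lower genes with the hepatoblast score (1.85e-05), and for the higher genes with the neutrophil score (0.00706). In E14.5 R1/2 the higher genes had p of 0.122 with the neutrophil score, 0.242 on the groups compared only, 0.166 without the prefix term, 0.627 with an estimated correlation, and 0.0719 with JC only in the opposite direction. The lower genes had 0.0136 with the hepatoblast score and 0.0308 with MS only. In E14.5 R3 p was 0.0111 and 3.42e-07 with the hepatoblast score and 0.00118 and 0.000194 with MS only. In E12.5 R3 the lower genes had 0.0892 with an estimated correlation.

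Directions of lists called in either fit turned in 34 cases, here with adjusted p. Quantile normalisation turned S phase (0.00286) and G2 and M phase genes (0.706) in E12.5 R3, G2 and M phase genes between the sorts at E12.5 (0.492) and ribosomal genes between R3 and R1/2 in wild type (1.36e-12) and Gata1s (5.44e-10), and upper-quartile scaling those of wild type (0.757). Quantile normalisation also turned Gata1 in E12.5 R3 (log2 0.24). JC only, which leaves 1 library of each genotype in E14.5 R1/2 and takes the spread from other groups, turned heme synthesis (0.526), red cell membrane (0.978), late maturation (0.0644), neutrophil (2.78e-06) and ribosomal genes (2.04e-06) there, and late maturation (5.04e-05) and red cell membrane (3.17e-09) between the days in R1/2. MS only, with 1 wild type library per group, turned glycolysis (0.297), neutrophil (0.000386) and S phase genes (0.0564) between those days, and ribosomal genes turned with the hepatoblast (0.378) and neutrophil (0.896) scores. Late maturation turned in E12.5 R1/2 with the neutrophil score (0.0043), and ribosomal genes in the mean with MS only (0.00118). By construction a score removes its own list: hepatoblast genes in E14.5 R3 (0.959) and between sorts at E14.5 (0.996), neutrophil genes between days in wild type (0.74) and Elane there (-0.13).

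Leaving out 1 library gave 460 to 1211 calls in E12.5 R1/2, 310 to 1277 in E14.5 R1/2, 0 to 4 for the days in R1/2, 943 to 1858 for the sorts at E12.5, 2142 to 4361 for the days in wild type, and 174 to 456 in all 4 combinations. Maturation p ranged from 2.74e-09 to 0.467 and 3.08e-08 to 0.468 in E12.5 R1/2, 9.33e-05 to 0.334 and 0.0106 to 0.828 in E14.5 R1/2, and 0.00323 to 0.903 and 9.16e-05 to 0.684 in E14.5 R3. Adjusted p for the days in R1/2 ranged from 1.37e-16 to 0.417 for red cell membrane, 1.46e-09 to 0.897 for late maturation, 2.54e-42 to 0.879 for neutrophil and 8.44e-12 to 0.391 for ribosomal genes. In E12.5 R1/2 it ranged from 1.23e-07 to 0.186 for red cell membrane. In E14.5 R1/2 it ranged from 0.00307 to 0.991 for mast cell, 3.61e-11 to 0.397 for neutrophil and 0.00074 to 0.966 for ribosomal genes. A library left alone in its group is assumed to vary like the other groups.

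Over all alternatives, gene results kept the call, and if called the direction, in 8867 cases, lost the call in 233 and gained it in 12. List results kept both in 6383, lost the call in 304, 108 of these with an estimated correlation, and gained it in 81. Calls of named genes ended without the prefix term for Alb, Trf and Prim1 in E12.5 R1/2, Trf and Itih2 in E12.5 R3, Gata1, Btg2 and Ube2c in E14.5 R1/2 and Alb between days in R3. JC only ended those of Gata1, Hbb-bh1, Bnip3, Trf and Prim1 in E12.5 R1/2 and of Gata1, Gata2, Cish, Junb, Btg2, Prc1, Ube2c, Hebp1, Tfrc, Slc25a37 and Ube2l6 in E14.5 R1/2. MS only ended those of Gata2, Osm, Ccne1, Alb and Trf in E12.5 R1/2, Trf and Itih2 in E12.5 R3 and Hbb-bh1 in E14.5 R1/2. Depths down to 7 M reads limit calls among low genes.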

Other observations

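Genes of the amino acid stress response were tested only after Slc7a11 was seen to stand out. In the mean over the 4 combinations Slc7a11 rose by 5.92 ± 0.25, Trib3 by 2.53 ± 0.23, Ddit4 by 2.26 ± 0.33, Atf5 by 1.98 ± 0.15, Cebpb by 1.17 ± 0.16, Eif4ebp1 by 0.92 ± 0.08 and Asns by 0.36 ± 0.08, but Sesn2 (0.19, adjusted p = 0.154) did not pass. Sesn2 rose in E14.5 R3 alone (1.59, 3.06e-05) and Asns in R1/2 alone (-0.04 and -0.30 in R3). Not called were Trib3 (0.28, 0.662) and Atf5 (0.77, 0.0568) in E12.5 R3, Ddit4 in E14.5 R1/2 and Cebpb in R1/2. Ppp1r15a fell by 0.82 ± 0.12 and Slc1a5 by 0.59 ± 0.10, while the messages of the regulators Atf4 (0.05, 0.487) and Ddit3 (-0.08, 0.592) did not pass.

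An active stress response may explain part of these changes. Of 42 listed genes not seen before the test 37 were measured, 17 higher and 7 lower, with a median of 0.14 and a camera p of 0.0098 in the mean. By combination p was 3.65e-05 in E12.5 R1/2, 3.68e-05 in E14.5 R1/2, 0.911 in E12.5 R3 and 0.0702 in E14.5 R3. With an estimated correlation p was 0.382 in the mean and 0.173 in each R1/2 comparison, so the hypothesis rests on the preset correlation and on R1/2, while Slc7a11 itself rose in all 4. Protein or translation was not measured.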
